A study of Mus musculus with 12 samples.

How the data were processed

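RNA from the anterior hard palate of mouse embryos was measured by RNA sequencing at embryonic days 14.5 (E14.5) and 16.5 (E16.5). Controls were compared with Shox2-Cre;R26R-Fgf8 mutants, in which Cre made from the Shox2 locus switches on an Fgf8 transgene. Each of the 4 groups held 3 samples, 12 in all. The labels do not say whether a sample is 1 embryo or a pool, so every p-value measures the spread between samples of unstated origin.

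The authors aligned reads to the mouse genome build mm9 with HISAT2 and deposited raw counts per gene from featureCounts. The submitters give no versions, annotation or strand setting. The authors also deposited DESeq2 comparison tables, from which the log2 fold change and the adjusted p value were read. The deposited tables of normalised and raw counts for the whole series, with 24 columns of per-sample values, were not used, since the per-sample files hold the same kind of counts with clearer labels. Genes are keyed by symbol alone, so no gene coordinates are given.

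Each sample's file held 24391 genes, of which 23322 symbols matched the reference names. The gene names of 27 genes appear as dates, 2 of them carried by more than 1 gene. These held 0.251% of all counts, stayed in the fits and are never named. Total counts ranged from 76417891 to 125996587 per sample, and the 10 most abundant genes took 3.98 to 4.97% of each library. Reads carried no molecular identifiers, so floors cover counting error only. No mitochondrially encoded gene was analysed here.

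Counts were fitted in R 4.3.3 with edgeR 4.0.16, using TMM factors, the filterByExpr filter and the quasi-likelihood test. Genotype was compared within each age on its 6 samples. The difference between the genotype effects at the 2 ages, and the change with age within each genotype, came from 1 fit of all 12 samples with 4 group means. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM (counts scaled to the same library total) are scaled by the TMM factors, and levels are given as mean ± SD (n = 3).

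Before the data were examined, 30 gene lists were fixed: FGF feedback and target genes, FGF ligands and receptors other than Fgf8, osteoblast and bone matrix, cartilage, osteoclast, BMP pathway, canonical Wnt response, Hedgehog pathway, palate mesenchyme patterning factors, cell cycle, cell cycle inhibitors and p53 response, TGF-beta pathway and matrix remodelling, tendon and fibrous tissue, oral and basal epithelium, cornified epithelium, nasal and ciliated epithelium, tooth, skeletal muscle, smooth muscle and pericyte, endothelium, macrophage and white blood cell, erythroid, Schwann cell and glia, neuron, melanocyte, adipocyte, immediate early and heat shock, hypoxia and glycolysis, mitochondrially encoded, and embryo sex. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with an estimated correlation and fry beside it. Lists of retinal genes and of motile cilium genes were added after the data had been seen, and 2 retinal genes are not reported here.

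The genes named were chosen by a rule fixed before the data were examined. It took Fgf8 and Shox2, the 10 called genes with the largest rise and the 10 with the largest fall at each age (6 each way for the other comparisons), and up to 4 called members of each list, or up to 2 members where none was called. The largest changes needed a mean log2 CPM of at least 1 and no overlap between the groups, and predicted genes without a common name were skipped. Genes named outside this rule are marked as such.

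Alternatives covered scaling (DESeq2 size factors and upper-quartile factors), tools (DESeq2 1.42.0 and limma-voom), low-count filters (none, or at least 5 CPM in 3 samples), a 2-fold minimum, a block for the replicate number, the set of samples in the fit and each library left out in turn. Chosen after the data had been seen were a term for the replicates numbered 3, replicates 1 and 2 alone, and a fit without E16.5 mutant libraries 1 and 3. That fit leaves 1 mutant library at E16.5, which is assumed to vary like the other groups.

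Whether replicate numbers pair samples was checked by correlating the deviations from the group mean of samples that share a number. Over 13463 genes with a mean log2 CPM above 1, the E16.5 groups gave 0.196, 0.241 and 0.695, and the controls of the 2 ages gave 0.149, 0.236 and 0.56. Over all 17550 genes past the filter, the E16.5 groups gave 0.104, 0.161 and 0.222, but the controls gave 0.0619, 0.0982 and 0.158. The E16.5 groups therefore pass a limit of 0.1 in both gene sets, and the controls across ages in the first set alone. So do E14.5 controls and E16.5 mutants, which no comparison sets side by side, in both sets (0.315, 0.369 and 0.542, then 0.147, 0.203 and 0.136), and E14.5 mutants and E16.5 controls in the first set (0.207, 0.156 and 0.636). In that last case, E14.5 mutants 1 and 2 correlated more with an E16.5 control of another number (highest 0.264 and 0.262). Passing the limit therefore does not show pairs. The first set, used first, was kept. With the replicate block, the E16.5 comparison called 6742 genes and the control age comparison 12748. The E14.5 groups gave 0.0786, 0.127 and 0.559 and were not treated as paired. Samples numbered 3, whose GEO sample numbers form a range apart from the rest, deviated together in all 6 pairs of groups (0.542 to 0.695). Within groups, chi-square per gene between libraries was 12.9 to 81.5, far above the value of 1 that technical repeats of a library give.

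The fits were tested on simulated data with 200 changed genes per comparison. Genes changed 2-fold were recovered in 83.6% of cases at E14.5, 72.7% at E16.5, 68.7% for the difference between ages, 73.1% for age in controls and 71.6% for age in mutants. Between 4.47 and 7.46% of the simulated calls were false.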

Results

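The data are gene counts from the anterior hard palate of mouse embryos, the bony front of the roof of the mouth. There were 3 control and 3 Fgf8 mutant samples at E14.5 and the same numbers at E16.5. Total counts were 78168839 to 125996587 per sample at E14.5 and 76417891 to 111946208 at E16.5. In a principal component analysis, the first component held 77.4% of the variance and set the ages apart. On it E16.5 mutant libraries 1, 2 and 3 lay at 60.95, 71.58 and 63.1, and the E16.5 controls at 109.4 to 115.6. The E14.5 samples lay at -102.1 to -82.24. The second component held 8.07% and ran from the E16.5 controls to E16.5 mutant libraries 1 and 3.

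The transgene and its driver were examined first, as a check on the labels. Fgf8, a secreted growth factor, rose from 0.320 ± 0.0969 to 10.9 ± 0.258 CPM at E14.5 (log2 fold change 5.12, SE 0.18, adjusted p = 3.93e-07). At E16.5 it rose from 0.375 ± 0.110 to 16.03 ± 2.02 CPM (log2 fold change 5.42, SE 0.22, adjusted p = 6.33e-06). Every mutant library was above every control library at both ages. Shox2, a homeobox transcription factor of the anterior palate, was at 181 ± 17.7 CPM in E14.5 controls and 215 ± 15.8 CPM in mutants, which did not pass the test (adjusted p = 0.0960). DESeq2 did call it there (adjusted p = 0.0477), as did a term for the replicates numbered 3 (adjusted p = 0.0137). At E16.5 Shox2 rose from 88.7 ± 5.40 to 139 ± 24.1 CPM (adjusted p = 0.00548). That call was lost in replicates 1 and 2 alone (adjusted p = 0.0597) and without mutant libraries 1 and 3 (adjusted p = 0.0682).

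**Figure D1:**
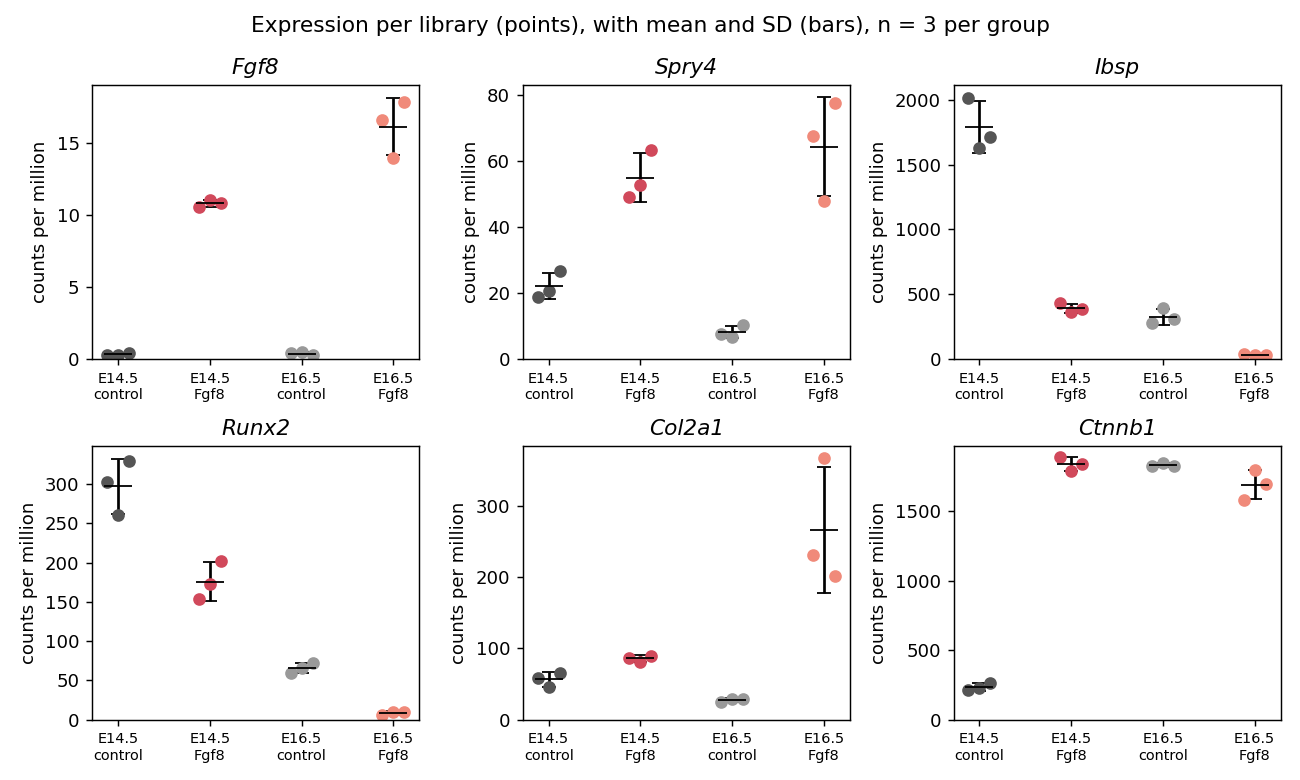
CPM (vertical axes, from 0) of 6 genes in each of the 12 libraries (points), with the mean and SD of each group of 3 (bars). Fgf8 and Spry4 are higher in the mutants at both ages, Ibsp and Runx2 are lower, Col2a1 is highest in the E16.5 mutants, and Ctnnb1 is low in the E14.5 controls alone.

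The E14.5 comparison asks what Fgf8 in the Shox2 domain changes when bone formation begins. Bone matrix genes were lower in the mutants. Ibsp, an acidic bone matrix protein, fell from 1798 ± 209 to 398 ± 34.5 CPM (log2 fold change -2.17, SE 0.09). Dmp1, a mineralisation regulator, fell from 45.5 ± 7.45 to 3.97 ± 1.41 CPM, and Spp1, osteopontin, fell from 143 ± 59.8 to 10.8 ± 5.97 CPM. Of 29 osteoblast and bone matrix genes, 23 fell and 0 rose (26 fell adjusted over the list alone), and the list was called (adjusted p = 2.01e-22, with an estimated correlation adjusted p = 0.174). Osteoclast genes fell in 6 of 13 cases (7 adjusted over the list alone), among them Mmp9, a matrix protease, from 113 ± 4.04 to 66.4 ± 4.58 CPM. The osteoclast list was called (adjusted p = 4.09e-05, with an estimated correlation adjusted p = 0.330).

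FGF feedback and target genes rose in 6 of 17 cases and fell in 1 (9 and 1 adjusted over the list alone). Spry4, an inhibitor of receptor tyrosine kinase signalling, rose from 22.1 ± 4.02 to 55.5 ± 7.38 CPM. Etv5, a transcription factor downstream of FGF signalling, rose from 50.1 ± 6.42 to 98.0 ± 3.26 CPM. The list was called (adjusted p = 0.000264, with an estimated correlation adjusted p = 0.515). Cell cycle genes rose in 5 of 32 cases and fell in 0 (8 rose adjusted over the list alone, list adjusted p = 4.77e-05, with an estimated correlation adjusted p = 0.4025). Rrm2, a subunit of ribonucleotide reductase, rose from 124 ± 3.62 to 158 ± 3.76 CPM.

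Among the largest E14.5 rises was that of Ctnnb1, the Wnt effector and adhesion protein beta-catenin, from 238 ± 26.3 to 1861 ± 44.7 CPM (log2 fold change 2.97, SE 0.08). Prrx1, a homeobox factor of limb and face mesenchyme, rose from 236 ± 32.2 to 1187 ± 133 CPM. Tbx3 rose from 17.0 ± 3.53 to 120.0 ± 13.0 CPM, Dlx2 from 8.40 ± 2.19 to 59.9 ± 8.40 CPM and Foxp1 from 11.02 ± 2.87 to 73.4 ± 8.90 CPM. Ctnnb1, Foxp1 and Tgfbr2 were lower in each E14.5 control than in any library of the other groups. Mn1, a regulator of palate growth, fell from 167 ± 22.9 to 43.6 ± 2.36 CPM. Of 27 palate mesenchyme patterning factors, 7 rose and 1 fell (10 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.0557). Leaving out control library 1 (adjusted p = 0.0211), control library 3 (0.0376) or mutant library 1 (0.0114) brought a call.

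Cartilage genes went both ways at E14.5, with 6 of 26 rising and 6 falling (7 and 8 adjusted over the list alone, list adjusted p = 0.889). Sox5, a cartilage transcription factor, rose from 3.54 ± 0.695 to 22.9 ± 2.48 CPM and Acan, aggrecan, from 12.3 ± 2.31 to 46.0 ± 0.886 CPM. Col11a2, a fibrillar collagen chain, fell from 281 ± 41.1 to 64.3 ± 3.92 CPM. The median of the cartilage list was -0.06 and its mean 0.14 on the log2 scale, so the 2 differ in sign. The TGF-beta and matrix remodelling list had 10 of 25 members lower and 1 higher (13 and 4 adjusted over the list alone, list adjusted p = 0.00265, with an estimated correlation adjusted p = 0.571). Fn1, fibronectin, fell from 1426 ± 100 to 802 ± 34.4 CPM, and Tgfbr2, a TGF-beta receptor, rose from 35.4 ± 6.36 to 154 ± 9.52 CPM.

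Endothelial genes fell in 9 of 16 cases at E14.5 (13 adjusted over the list alone, list adjusted p = 7.52e-08, with an estimated correlation adjusted p = 0.330). Tie1, an endothelial receptor, fell from 83.2 ± 2.79 to 64.9 ± 3.21 CPM. Smooth muscle and pericyte genes fell in 5 of 13 cases and rose in 1, the same adjusted over the list alone (list adjusted p = 0.00961, with an estimated correlation adjusted p = 0.571). Adipocyte genes fell in 4 of 8 cases, also 4 adjusted over the list alone (list adjusted p = 0.000137, with an estimated correlation adjusted p = 0.174). Car3, a carbonic anhydrase, fell from 71.7 ± 1.79 to 23.5 ± 2.40 CPM. Immediate early and heat shock genes fell in 5 of 18 cases (11 adjusted over the list alone, list adjusted p = 0.000463, with an estimated correlation adjusted p = 0.515). Oral and basal epithelial genes rose in 4 of 24 cases (6 adjusted over the list alone, list adjusted p = 1.17e-05, with an estimated correlation adjusted p = 0.571).

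Skeletal muscle genes fell in 1 of 22 cases (4 adjusted over the list alone). That list was called (adjusted p = 0.00576, with an estimated correlation adjusted p = 0.571), but not without control library 2 (adjusted p = 0.0775). Macrophage and white blood cell genes fell in 4 of 21 cases (5 adjusted over the list alone, list adjusted p = 0.0130, with an estimated correlation adjusted p = 0.571). The call was lost without control library 1 (adjusted p = 0.0713) and without mutant library 2 (adjusted p = 0.198). Rises and falls in the other lists with a called member were 2 and 3 of 26 for FGF ligands and receptors, 3 and 5 of 27 for the BMP pathway, 2 and 4 of 22 for Wnt, 1 and 1 of 15 for Hedgehog, 1 and 1 of 17 for cell cycle inhibitors, 2 and 3 of 16 for tendon, 1 and 0 of 17 for nasal and ciliated epithelium, 0 and 1 of 10 for tooth, 1 and 1 of 13 for Schwann cell and glia, and 0 and 1 of 17 for hypoxia. Adjusted over the list alone, these were 3 and 4, 4 and 7, 4 and 5, 1 and 3, 2 and 2, 2 and 5, 1 and 0, 0 and 1, 2 and 4, and 0 and 1. No member was called of 10 cornified, 11 erythroid, 16 neuron or 4 melanocyte genes tested. Adjusted over the list alone, 1 neuron gene rose and 5 fell.

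None of the E14.5 lists for which only rises and falls are given was called, though leaving out 1 library brought a call for some. Without control library 1 these were FGF ligands and receptors (adjusted p = 0.0186), Wnt (0.00591), Hedgehog (0.0449) and embryo sex (0.0263). Without control library 2 they were Hedgehog (0.04465), nasal and ciliated epithelium (0.00477), Schwann cell and glia (0.0358) and neuron (0.000989). The nasal and ciliated list was also called without control library 3 (0.0492) and mutant library 2 (0.0139), the Wnt list without mutant library 2 (0.0475) or 3 (0.0452) and the Hedgehog list without mutant library 3 (0.0452).

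At E14.5 Xist, the X-inactivation RNA, fell from 790.1 ± 79.7 to 493 ± 40.3 CPM, with 4 of 6 genes in the embryo sex list higher and 1 lower, also when adjusted over the list alone (list not called, adjusted p = 0.188). At E16.5 Xist rose from 395 ± 69.9 to 894 ± 6.22 CPM, with 1 higher and 4 lower, again also adjusted over the list alone (list not called, adjusted p = 0.0875). The groups thus differed in markers of embryo sex as well as in genotype, in opposite ways at the 2 ages.

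In all, edgeR called 1252 of 16650 genes at E14.5, 491 higher and 761 lower, of which 64 and 115 changed at least 2-fold. The count was 2120 with DESeq2 and 2938 with a term for the replicates numbered 3. It was 666 without control library 1, 630 without control library 3, 526 without mutant library 1 and 673 without mutant library 2.

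The E16.5 comparison asks the same of the later palate. Bone genes were again lower. Runx2, the master transcription factor of osteoblasts, fell from 65.3 ± 6.41 to 8.59 ± 2.07 CPM (log2 fold change -2.93, SE 0.18). Sp7, which acts after it, fell from 41.3 ± 1.84 to 7.44 ± 1.24 CPM, and Col1a2, a chain of type I collagen, from 2617 ± 183 to 377 ± 149 CPM. Ibsp fell from 323 ± 61.0 to 33.7 ± 1.24 CPM. Of 30 osteoblast and bone matrix genes, 17 fell and 2 rose, the same adjusted over the list alone, and the list was called (adjusted p = 1.02e-05, with an estimated correlation adjusted p = 0.148).

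Cartilage genes rose in 12 of 25 cases and fell in 3 at E16.5, the same adjusted over the list alone. Col2a1, the main cartilage collagen, rose from 27.5 ± 2.91 to 264 ± 86.5 CPM (log2 fold change 3.27, SE 0.22). Col9a1 rose from 10.1 ± 1.01 to 71.2 ± 11.5 CPM, and Cytl1, a secreted protein of cartilage, from 0.119 ± 0.143 to 12.5 ± 7.28 CPM. The cartilage list was called (adjusted p = 0.0170, with an estimated correlation adjusted p = 0.219), but not with the replicate block (adjusted p = 0.0641) nor without mutant libraries 1 and 3 (adjusted p = 0.0961).

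FGF feedback and target genes rose in 7 of 17 cases and fell in 2 at E16.5 (9 and 2 adjusted over the list alone). Spry4 rose from 8.08 ± 1.79 to 63.8 ± 15.0 CPM and Dusp6, a phosphatase that turns off ERK, from 87.3 ± 7.07 to 209.9 ± 6.54 CPM. The list was called (adjusted p = 0.0084, with an estimated correlation adjusted p = 0.454), but not without mutant libraries 1 and 3 (adjusted p = 0.106). Genes of the BMP pathway rose in 11 of 27 cases and fell in 2 (13 and 2 adjusted over the list alone, list adjusted p = 0.001, with an estimated correlation adjusted p = 0.192). Smad9 rose from 10.9 ± 0.576 to 72.0 ± 15.6 CPM and Msx1, a homeobox factor, from 15.6 ± 3.87 to 67.5 ± 19.3 CPM. Palate mesenchyme patterning factors rose in 16 of 27 cases and fell in 3 (18 and 3 adjusted over the list alone, list adjusted p = 3.7e-05, with an estimated correlation adjusted p = 0.307). Tbx2 rose from 57.8 ± 2.29 to 201 ± 22.3 CPM.

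Epithelial genes were lower in the E16.5 mutants. Nasal and ciliated epithelium genes fell in 14 of 19 cases (14 fell and 1 rose adjusted over the list alone, list adjusted p = 7.78e-07, with an estimated correlation adjusted p = 0.148). Sec14l3 fell from 273 ± 4.07 to 70.7 ± 3.001 CPM and Foxa1, a transcription factor of airway epithelium, from 85.7 ± 6.66 to 28.2 ± 3.68 CPM. Cornified epithelium genes fell in 11 of 13 cases (12 adjusted over the list alone, list adjusted p = 3.5e-05, with an estimated correlation adjusted p = 0.148). Krt10, a keratin of differentiating epidermis, fell from 786 ± 78.8 to 406 ± 30.4 CPM, and Krt76, a keratin of the hard palate, from 253 ± 10.3 to 33.5 ± 3.43 CPM. Oral and basal epithelium genes fell in 10 of 24 cases (13 adjusted over the list alone, list adjusted p = 6.38e-05, with an estimated correlation adjusted p = 0.5025). That call was lost without mutant libraries 1 and 3 (adjusted p = 0.170).

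Endothelial genes rose in 14 of 16 cases at E16.5 (15 adjusted over the list alone, list adjusted p = 3.67e-06, with an estimated correlation adjusted p = 0.284). Cldn5, an endothelial tight junction protein, rose from 15.2 ± 0.869 to 25.2 ± 2.23 CPM. Cell cycle genes rose in 14 of 32 cases (18 adjusted over the list alone, list adjusted p = 1.02e-05, with an estimated correlation adjusted p = 0.284). Rrm2 rose from 81.9 ± 3.99 to 108 ± 3.14 CPM. Vegfa, the endothelial growth factor, fell from 104 ± 5.85 to 27.4 ± 7.43 CPM. It belongs to the hypoxia list, in which 6 of 17 genes fell (7 adjusted over the list alone, list adjusted p = 0.0223, with an estimated correlation adjusted p = 0.454). The hypoxia call was lost without mutant library 1 (adjusted p = 0.0615) and without mutant libraries 1 and 3 (adjusted p = 0.170).

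Neuron genes rose in 11 of 16 cases (15 adjusted over the list alone, list adjusted p = 0.001, with an estimated correlation adjusted p = 0.5025). Tubb3, a neuronal tubulin, was at 11.8 ± 1.46 CPM in controls and at 88.1, 17.6 and 48.3 CPM in mutant libraries 1, 2 and 3. Prph, a neuronal intermediate filament, rose from 0.799 ± 0.256 to 4.02 ± 0.568 CPM, with library 2 at the level of library 3. Without libraries 1 and 3 the list was not called (adjusted p = 0.615). Retinal genes stood out in libraries 1 and 3: Fgf15, a secreted growth factor, was at 40.9 CPM in mutant library 1, 0.345 CPM in library 2 and 21.2 CPM in library 3.

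**Figure D2:**
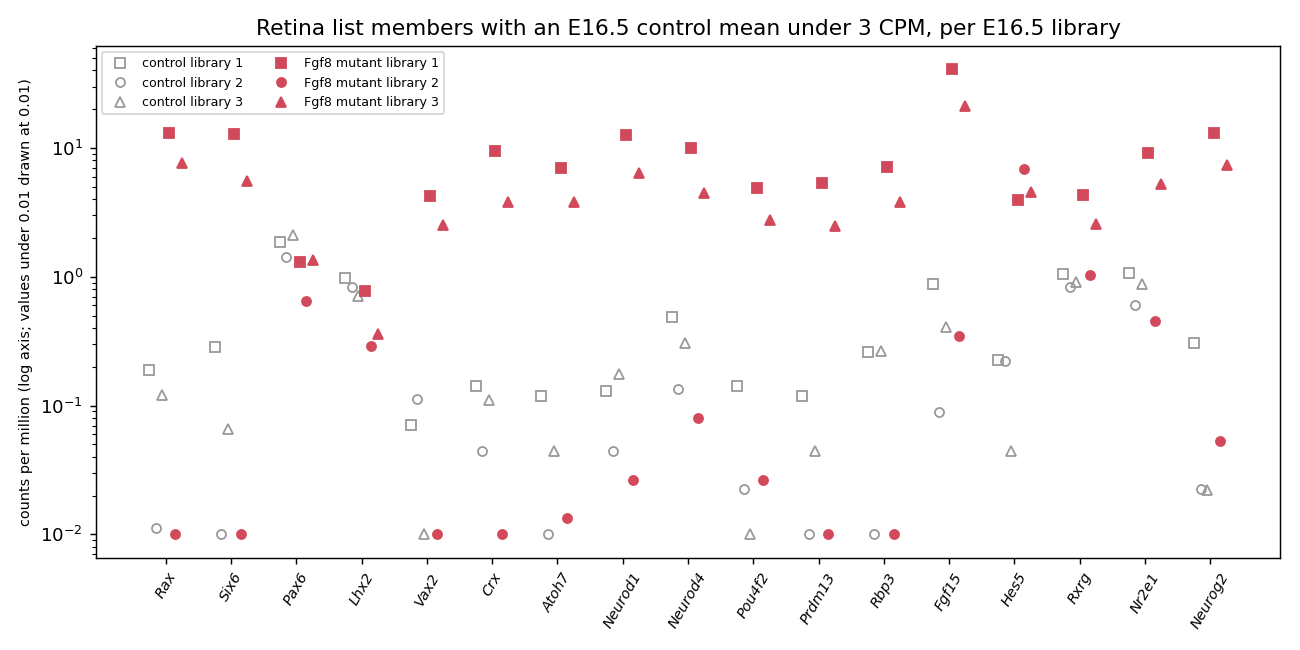
CPM (vertical log axis, values under 0.01 drawn at 0.01) of the 17 retina list genes (horizontal axis) with an E16.5 control mean under 3 CPM, in each E16.5 library (points, shapes by library number). In 15 of them mutant libraries 1 and 3 lie at least 2 times above the highest control, while Pax6 and Lhx2 do not.

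Adipocyte genes fell in 4 of 7 cases at E16.5 (5 adjusted over the list alone). The list was called (adjusted p = 0.0460, with an estimated correlation adjusted p = 0.284), but not without control library 3 (adjusted p = 0.0521), mutant library 2 (adjusted p = 0.0566), mutant library 3 (adjusted p = 0.0642) nor with the replicate block (adjusted p = 0.0641) or without mutant libraries 1 and 3 (adjusted p = 0.1495). Rises and falls in lists that were not called were 5 and 6 of 25 for FGF ligands and receptors, 4 and 1 of 12 for osteoclast, 10 and 3 of 22 for Wnt, 3 and 4 of 15 for Hedgehog, 0 and 4 of 18 for cell cycle inhibitors, 6 and 4 of 25 for TGF-beta, 3 and 3 of 16 for tendon, 3 and 0 of 7 for tooth, 0 and 4 of 23 for skeletal muscle, 7 and 1 of 14 for smooth muscle, 0 and 2 of 21 for macrophage, 1 and 2 of 13 for Schwann cell and glia, and 1 and 2 of 18 for immediate early genes. Adjusted over the list alone, these were 6 and 7, 4 and 1, 10 and 3, 3 and 4, 0 and 4, 6 and 5, 3 and 4, 3 and 0, 0 and 3, 9 and 2, 0 and 2, 1 and 1, and 1 and 2. No member was called of 11 erythroid or 2 melanocyte genes tested. Leaving out 1 library brought a call for tooth (adjusted p = 0.0421 without control library 1, 0.0374 without control library 2, 0.0121 without mutant library 1), skeletal muscle (0.0368 without control library 1, 0.0341 without mutant library 1) and smooth muscle (0.0421 without control library 1). It also did so for immediate early genes (0.0214 without mutant library 2) and embryo sex (0.0306 without mutant library 1). Fn1 fell from 571 ± 41.9 to 82.6 ± 26.5 CPM, Lox from 443 ± 48.3 to 75.5 ± 11.9 CPM and Hhip, a Hedgehog inhibitor, from 44.7 ± 6.36 to 7.48 ± 1.57 CPM.

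**Figure D3:**
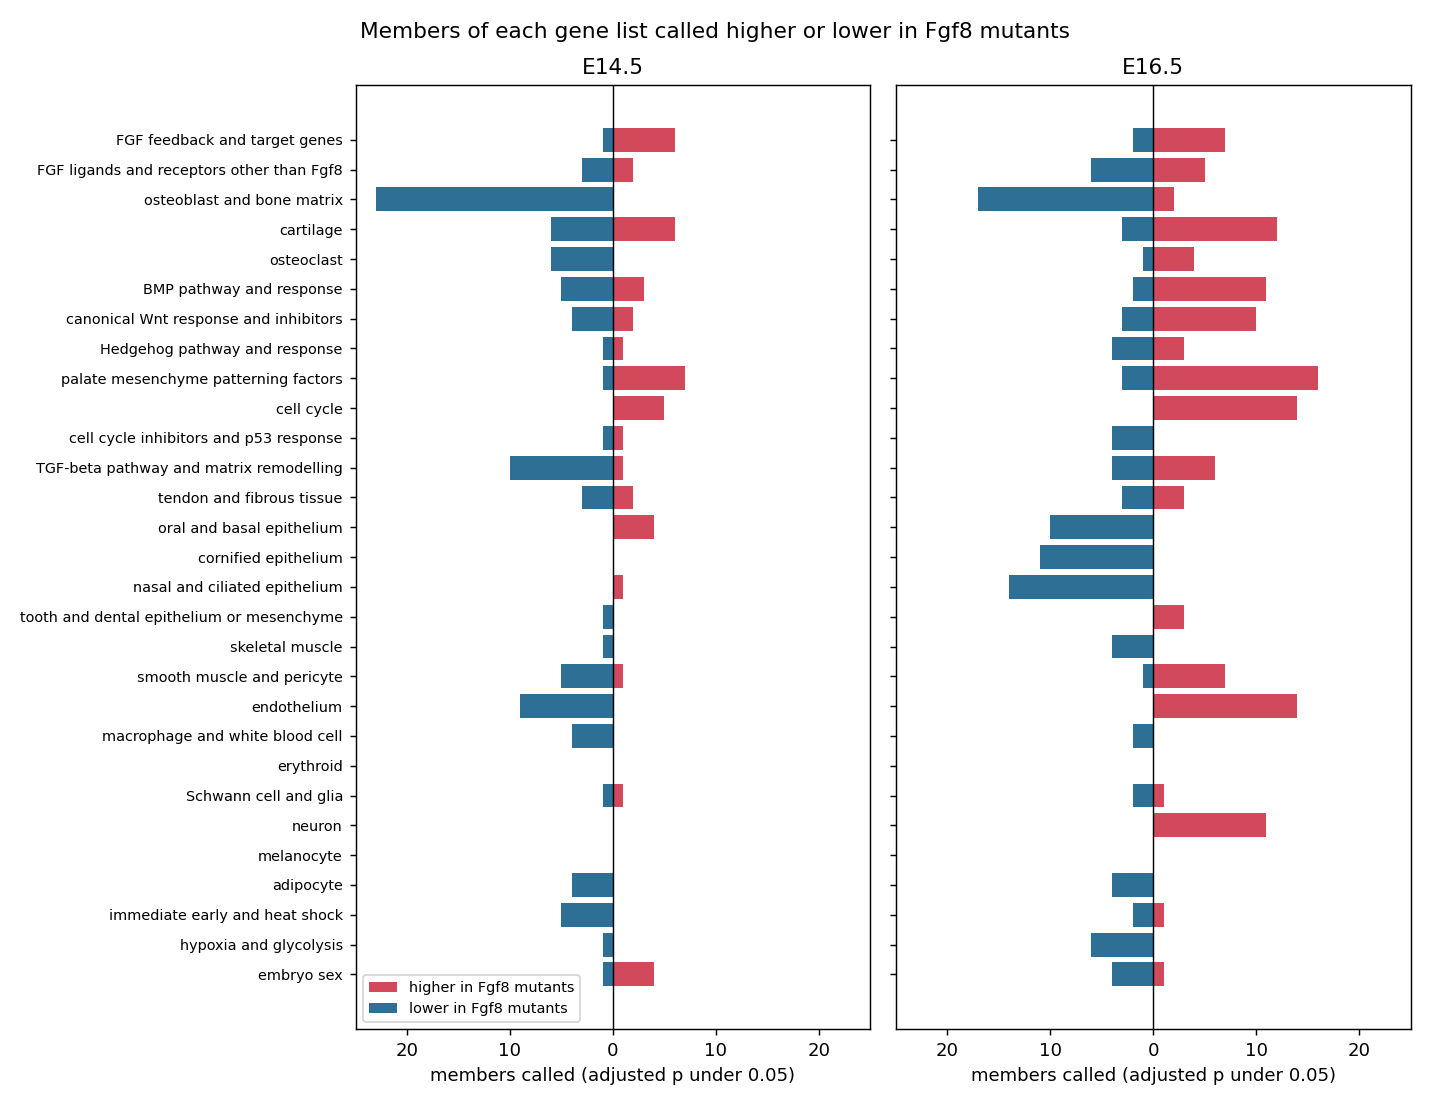
Members of each gene list (vertical axis) called higher (right) or lower (left) in Fgf8 mutants, as numbers of genes (horizontal axis), at E14.5 and E16.5. Osteoblast genes are lower at both ages, with 23 and 17 falling, while endothelial genes are lower at E14.5 (9 genes) and higher at E16.5 (14 genes).

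At E16.5 edgeR called 4793 of 17169 genes, 2099 higher and 2694 lower, of which 538 and 1027 changed at least 2-fold. The count was 3079 without control library 1, 2781 without control library 2, 2286 in replicates 1 and 2 alone and 2698 without mutant libraries 1 and 3.

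The overlap asks whether the same genes respond at both ages. Of 16398 genes tested at both, 535 were called at both, 382 in the same direction and 153 in opposite directions. Genes higher at both ages numbered 206 against 62.0 for independent lists, and genes lower at both numbered 176 against 112. Genes lower at E14.5 and higher at E16.5 numbered 114 against 95.3, and those higher and then lower 39 against 72.6. Across genes, which are not independent replicates, the log2 fold changes at the 2 ages correlated with r = 0.041 (Spearman rho = -0.026) over all genes and r = 0.68 among those called at both. With DESeq2, 577 genes were shared in the same direction and 402 in opposite directions, and with the replicate block 919 and 612.

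The interaction tests whether the genotype effect differs between the ages. It did for 3921 of 17550 genes, with 1750 more positive at E16.5 and 2171 more negative (2142 and 1947 with upper-quartile factors, 2399 and 2324 without E16.5 mutant library 2), for 6055 with the replicate block, for 1961 in replicates 1 and 2 alone and for 2017 without E16.5 mutant libraries 1 and 3. Ctnnb1 rose at E14.5 but had a log2 fold change of -0.11 at E16.5, a difference of -3.10 (SE 0.11). Cytl1 differed by 5.96 (SE 0.84), Cldn2, a tight junction protein, by -3.30 (SE 0.16) and Sprr1b, a cornified envelope protein, by -4.53 (SE 0.80). Sprr1b did not pass the low-count filter at E14.5 and had a log2 fold change of -0.84 at E16.5. Its difference thus rests mostly on low counts at E14.5. The endothelial list differed most clearly of the 13 called by camera (adjusted p = 4.24e-11, with an estimated correlation adjusted p = 0.159), with 14 of 16 members more positive at E16.5. The osteoblast list as a whole was not called to differ (adjusted p = 0.177), with 12 members more positive and 7 more negative. Embryo sex markers differed between the genotypes in opposite ways at the 2 ages, so sex was not set apart from genotype in this test.

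The change from E14.5 to E16.5 in controls covers maturation, but embryo sex and the tissue dissected were not set apart from it. Of 6 embryo sex genes, 4 rose and 1 fell, also adjusted over the list alone (list not called, adjusted p = 0.262). The comparison called 11652 of 17550 genes, 6016 higher and 5636 lower at E16.5, of which 3158 and 1497 changed at least 2-fold. With upper-quartile factors it called 5539 higher and 6405 lower. All 13 tested cornified epithelium genes rose (list adjusted p = 8.29e-08, with an estimated correlation adjusted p = 0.0929), and so did all 19 nasal and ciliated genes (list adjusted p = 5.61e-09, with an estimated correlation adjusted p = 0.0929). Acer1, a ceramidase, was at 16.5 ± 1.94 CPM at E16.5 and had 0 counts in all 3 E14.5 controls, which allows up to 0.00967 CPM over the group. Osteoblast genes fell in 23 of 30 cases and rose in 4 (list adjusted p = 1.02e-06, with an estimated correlation adjusted p = 0.0929). Adjusted over the list alone, the counts for the cornified, nasal and osteoblast lists did not change. Hbb-y, an embryonic globin, fell from 188 ± 31.9 to 3.01 ± 0.354 CPM. It belongs to the erythroid list, in which 5 of 11 genes fell and 1 rose, also adjusted over the list alone, and which was not called (adjusted p = 0.0883).

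In mutants, the same interval called 9059 genes, 4769 higher and 4290 lower, of which 2368 and 515 changed at least 2-fold, and with upper-quartile factors 4571 and 4657. Runx2 fell from 175 ± 25.1 to 8.65 ± 2.19 CPM, Sp7 from 106 ± 10.2 to 7.48 ± 1.35 CPM and Mmp9 from 65.6 ± 4.66 to 2.56 ± 0.498 CPM. Sdr9c7, a dehydrogenase of the skin barrier, was at 15.4 ± 1.26 CPM at E16.5 and had 0 counts in all 3 E14.5 mutants, which allows up to 0.0125 CPM over the group. All 13 tested cornified genes rose and 20 of 30 osteoblast genes fell and 5 rose (13, 21 and 5 adjusted over the list alone).

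The E16.5 genotype effect was then set against the age change in controls. Across 17166 genes, its covariance with the age effect in controls was -0.698, with r = -0.58. Because the E16.5 controls enter both, unchanged groups were simulated 20 times and gave -0.0318 (SD 0.00134), which leaves -0.666. Genes that rose with age in controls thus tended to be lower in E16.5 mutants than in controls. A difference in stage or dissection between the E16.5 groups would give this too, and the simulated groups hold no such difference. At E14.5 the covariance was 0.151 against 0.0256 for unchanged groups. There the E14.5 controls enter both effects, so a shift of those controls alone would also give a positive value.

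In the authors' own tables, 2058 genes had an adjusted p under 0.05 at E14.5 and 5536 at E16.5. Of the edgeR calls, 1235 and 4722 were among them, all in the same direction. Across genes, the log2 fold changes from the 2 sources correlated with r = 0.84 at E14.5 and 0.91 at E16.5. A correlation does not show that their sizes match. At E14.5 the deposited value was -2.01 for Ibsp against -2.17 here, but -0.69 for Spp1 against -3.73. At E16.5 it was 1.38 for Cytl1 against 6.73 here.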

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

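The tests of scaling, of the replicates numbered 3, of draws that part the pairs, of retinal genes and of ciliated cell number were chosen only after their results had been seen. The test of the E16.5 genotype effect against that at E14.5 was planned, and it called 3921 genes with edgeR. Of 100 draws of genotype labels within each age, 1, the real one, called as many, and the highest of the others called 3090. For labels exchanged freely within each age, this excludes only that genotype had no effect at either age. Exchanging labels also removes any genotype effect shared by the ages, so the draws cannot decide whether that effect differs between the ages. The E16.5 samples passed the limit for pairing by number, but so did E14.5 controls and E16.5 mutants, so passing does not show pairs. Among the 37 draws that part all 3 same-numbered E16.5 pairs as the real one does, 1, the real one, again called as many. The draws that part fewer pairs called at most 63. Of the 13 other draws with calls, 6 kept the E16.5 genotypes intact or all swapped and 7 the E14.5 genotypes, and the first 6 called the most genes. They point to a structure of the samples, the genotype difference at each age.

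For genotype at each age and for age within each genotype, the 3 against 3 samples make 10 splits, too few for a share under 0.05. The real split, 1 of the 10, called 1252 genes at E14.5 with edgeR (3866 at an unadjusted p under 0.05) and the highest other split called 0 (1904 unadjusted). At E16.5 these were 4793 (6770 unadjusted) against 0 (1541 unadjusted), and 4 of the 10 splits part all 3 same-numbered pairs as the real one does. Fitted on the 6 samples compared, the age change called 11713 against 0 (211 unadjusted) in controls and 7975 against 0 (504 unadjusted) in mutants.

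Gene lists whose genotype effect differed between the ages, by camera, were endothelium (adjusted p = 4.24e-11), nasal and ciliated epithelium (2.69e-07), oral and basal epithelium (4.09e-07), neuron (0.000505), BMP pathway (0.0005998), cornified epithelium and palate mesenchyme patterning factors (0.00349 each), osteoclast and smooth muscle (0.00478 each), cartilage (0.0176), and Wnt, tooth and Schwann cell and glia (0.0341 each). With an estimated correlation the adjusted p lay between 0.159 and 0.515, and no list was called (5 at an unadjusted p under 0.05, and 15 by fry). Without E16.5 mutant libraries 1 and 3 the neuron (0.2105), palate (0.0588), Wnt (0.281) and Schwann (0.0776) calls were lost, and fry did not call neuron (0.0609). Cartilage lost its call with a term for the replicates numbered 3 (0.0560) and in replicates 1 and 2 alone (0.0646), and osteoclast with the 5 CPM filter (0.0637).

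The Wnt, tooth and Schwann cell calls lay near the threshold, and were lost in several settings and on leaving out any 1 of several libraries. With upper-quartile scaling each had an adjusted p of 0.0606. With the 5 CPM filter it was 0.0765, 0.0637 and 0.1146, with the term for the replicates numbered 3 it was 0.0668, 0.0668 and 0.0560, and in replicates 1 and 2 alone 0.0891, 0.139 and 0.0685. With the replicate block it was 0.0878 for Wnt and for tooth. Over all alternatives it ranged from 0.0174 to 0.515 for Wnt, 0.00178 to 0.325 for tooth and 0.00852 to 0.456 for Schwann cells. The Wnt call was lost without E14.5 control library 2 (adjusted p = 0.0583) or 3 (0.0725), E14.5 mutant library 1 (0.0708), E16.5 control library 2 (0.0693) and E16.5 mutant library 1 (0.0699) or 3 (0.0901). The tooth call was lost without E14.5 control library 2 (0.0606) or 3 (0.0613), E14.5 mutant library 1 (0.0799), E16.5 control library 3 (0.0502) and E16.5 mutant library 2 (0.113) or 3 (0.0808). The Schwann cell call was lost without E14.5 control library 1 (0.0677), E14.5 mutant library 2 (0.0926) or 3 (0.0547), E16.5 control library 2 (0.0763) or 3 (0.0502) and E16.5 mutant library 1 (0.0750) or 2 (0.0960).

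Of the genes named, 129 had a genotype effect that differed between the ages in edgeR's test of the difference, given here as the E16.5 minus the E14.5 log2 fold change. Among palate mesenchyme patterning genes it was -1.35 for Tbx3, 0.59 for Inhba, 0.70 for Prrx2, 0.92 for Tbx2 and 1.004 for Lhx6. Among cartilage genes it was -0.95 for Sox5, -0.69 for Col11a1, 1.62 for Col9a3, 2.63 for Col2a1 and 5.96 for Cytl1. Among osteoblast and bone matrix genes it was -2.21 for Runx2, -1.83 for Col1a2, -1.16 for Sp7, -1.11 for Ibsp, -0.63 for Ifitm5, 0.76 for Alpl and 1.84 for Spp1. Among macrophage and white blood cell genes it was -0.82 for Cd14 and 4.29 for Mpo. Among FGF feedback and target genes it was 0.35 for Spry1, 0.88 for Dusp6 and 1.63 for Spry4. Among FGF ligand and receptor genes it was -2.10 for Fgf18, -1.18 for Fgfbp1, 0.54 for Fgfr1, 0.82 for Fgfrl1 and 6.22 for Fgf15. Among osteoclast genes it was -1.09 for Mmp9, 0.73 for Itgb3 and 2.21 for Atp6v0d2. Among BMP pathway genes it was 0.66 for Smad6, 0.82 for Bambi, 2.03 for Msx1, 2.12 for Bmp5 and 3.06 for Smad9. Among Wnt response and inhibitor genes it was -0.41 for Kremen1, 0.68 for Notum, 0.95 for Frzb, 1.27 for Tcf7 and 1.92 for Dkk1. Among Hedgehog pathway genes it was -2.13 for Hhip, -0.56 for Foxl1, -0.38 for Foxf2 and 1.24 for Shh. Among cell cycle genes it was -0.42 for Ccne2 and 0.39 for Mcm3. Among TGF-beta and matrix genes it was -2.09 for Tgfbr2, -1.98 for Fn1, -1.53 for Lox, 0.54 for Tnc and 0.86 for Timp3. Among tendon and fibrous tissue genes it was 0.63 for Col12a1 and 0.64 for Col5a1. Among oral and basal epithelial genes it was -1.55 for Cldn3, -1.51 for Cldn7, -1.38 for Krt8, -1.29 for Krt18, -0.95 for Krt6a, -0.91 for Perp, -0.81 for Epcam and -0.73 for Sfn. Among cornified epithelial genes it was -4.53 for Sprr1b (filtered out for low counts at E14.5), -1.14 for Krt10, -1.04 for Krtdap and -0.83 for Sbsn. Among nasal and ciliated genes it was -2.36 for Sec14l3, -2.02 for Tmem212, -1.85 for Bpifa1, -1.83 for Ccdc39 and -1.71 for Foxa1. Among tooth genes it was 2.06 for Ambn. Among smooth muscle and pericyte genes it was -0.44 for Myh11, 0.76 for Acta2, 0.98 for Cspg4 and 1.36 for Kcnj8. Among endothelium genes it was 0.77 for Plvap, 0.78 for Tek, 0.88 for Cldn5, 0.92 for Emcn, 0.92 for Tie1, 1.10 for Flt1 and 1.12 for Kdr. Among Schwann cell and glia genes it was -0.83 for Erbb3, -0.51 for Mbp and 0.84 for Ngfr. Among neuron genes it was 1.87 for Syt1, 1.97 for Rbfox3, 2.01 for Dcx, 2.16 for Tubb3, 2.31 for Prph, 2.98 for Stmn2, 5.83 for Stmn3 and 6.35 for Elavl3. Among adipocyte genes it was -0.97 for Cd36, 0.90 for Fabp4 and 0.92 for Pparg. Among immediate early and heat shock genes it was -0.76 for Hsph1, 1.14 for Klf2 and 2.60 for Egr3. Among embryo sex genes it was -2.29 for Uty, -2.15 for Ddx3y, -2.09 for Eif2s3y, -2.08 for Kdm5d and 1.84 for Xist. These genes mark embryo sex, which was not set apart from genotype, so they show no genotype effect of their own. Among cell cycle inhibitor and p53 genes the difference was -1.12 for Fas, -0.70 for Trp53inp1 and -0.44 for Mdm2. Among hypoxia and glycolysis genes it was -2.09 for Vegfa and -0.61 for Egln3. Outside the lists it was -3.66 for Als2cr12, -3.30 for Cldn2, -3.29 for Wdr38, -3.27 for Lipi, -3.23 for Fam47e, -3.10 for Ctnnb1, -2.98 for Foxp1, -2.79 for Foxp2, -1.78 for Creb3l1 and -1.65 for Cdk6. It was positive, at 0.80 for Adgrd1, 1.002 for Hrc, 2.19 for Mfi2, 2.68 for Stk32b, 4.27 for Celsr3, 4.69 for Cbln4, 5.50 for Hes5, 5.51 for Ina, 5.74 for Stmn4 and 6.48 for Rpl29. Without E16.5 mutant libraries 1 and 3, which leaves 1 mutant library at that age, 94 of the 129 kept their call and 35 lost it. For Elavl3, Fgf15, Stmn3 and Ina the adjusted p was then 0.970, 0.888, 0.845 and 0.450. The others that lost it were Stmn4 (0.354), Mpo (0.350), Celsr3 (0.153), Stmn2 (0.0938), Tubb3 (0.0978), Dcx (0.424), Rbfox3 (0.0662), Syt1 (0.106), Spp1 (0.0761), Kcnj8 (0.0742) and Fabp4 (0.129). Further ones were Adgrd1 (0.143), Notum (0.0625), Inhba (0.0917), Spry1 (0.0619), Kremen1 (0.131), Ccne2 (0.0698), Myh11 (0.103), Mbp (0.0750), Foxl1 (0.199) and Ifitm5 (0.153). The rest were Col11a1 (0.175), Sfn (0.322), Epcam (0.139), Cd14 (0.0935), Erbb3 (0.118), Perp (0.0871), Krt6a (0.0653), Krtdap (0.109), Mmp9 (0.0558) and Fgfbp1 (0.0673). A call lost with fewer libraries does not show that the difference came from them. Of the 35 differences, 4 (Spp1, Adgrd1, Ccne2 and Cd14) were then at least as large, 19 between 0.5 and 1 times as large, and 12 (Elavl3, Fgf15, Stmn3, Stmn4, Ina, Celsr3, Stmn2, Tubb3, Dcx, Syt1, Col11a1 and Sfn) under 0.5 times as large or of the other sign. With limma-voom it was, for Elavl3, Fgf15, Stmn3 and Ina, 0.329, 0.399, 0.341 and 0.452, and in replicates 1 and 2 alone 0.144, 0.1445, 0.134 and 0.172. The lowest over the alternatives were 0.000106, 5.47e-05, 0.000111 and 8.46e-05. Ina also lost its call without E14.5 control library 1 (0.0534), E14.5 mutant library 1 (0.0525) and E16.5 control library 2 (0.0525). Rpl29 was at 1.91 to 34.9 CPM in E14.5 controls, and lost its call in replicates 1 and 2 alone (0.0621, range over the alternatives 3.48e-06 to 0.0621).

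Ctnnb1 was low in the E14.5 controls, at 213 to 265 CPM, and at 1584 to 1888 CPM in every other library, and so were Foxp1 (7.76 to 13.1 CPM, against 66.2 CPM or more elsewhere) and Tgfbr2 (28.8 to 41.4 CPM, against 145 CPM or more elsewhere). Its log2 fold change at E14.5 was 3.05 in replicates 1 and 2 alone, which argues against the replicates numbered 3 as the whole source. It was 2.96 at the lowest of 3 scalings, while the median of all genes lay at 0.00818 to 0.0194. Scaling shifts all genes of a library alike, so these values argue against it as the source for Ctnnb1. An early onset of the normal age change in mutants stays open. Across all genes, the E14.5 genotype effect covaried with the control age effect by 0.1253 beyond unchanged groups (SD 0.00113). That value covers all genes rather than Ctnnb1, and a difference in stage between litters would give it too. So would any shift of the E14.5 controls alone, since they enter both effects. The covariance therefore cannot tell a change in the mutants from one in these controls. A genetic difference between the control and mutant embryos at any of the 3 genes was not tested.

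Retinal genes were raised in E16.5 mutant libraries 1 and 3: of the 17 list genes with a control mean under 3 CPM, 15 were at least 2 times the highest control in both, with Fgf15 at 40.9 CPM in library 1. Of these 15, 1 (Hes5) was also raised in mutant library 2, but 1 library, and genes seen first in the other 2, decide nothing on Fgf8 turning on retinal genes. Library 3 held these genes at a median of 0.545 times library 1 (quartiles 0.489 and 0.58). Retinal tissue in the dissection may be the source, but it cannot be told apart from Fgf8 turning on these genes, since Pax6 (1.30 and 1.34 CPM against a highest control of 2.11) and Lhx2 were not raised. The list of 24 was written partly from genes already seen to be raised, 7 of its genes had a control mean of 3 CPM or more, and no sort would have removed such cells.

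Motile cilium genes parted at E16.5: of 76 tested, 48 fell, 1 (Ccdc40, chosen after its values were seen) rose and 27 did not pass. Their log2 fold changes had quartiles 1.45 apart, against a median standard error of 0.122. Fewer ciliated cells cannot be told apart from an effect on the genes themselves, since expression in other cells, which was not measured, would weaken some of the falls and part the genes too. Transcript GC content and length gave an R squared of 0.166. Its bootstrap interval of 0.0699 to 0.317 (2000 draws) spans the limit of 0.2 set beforehand, so the test cannot place it on either side. Even at 0.317, GC content and length as fitted would leave most of the spread of the 76 genes unexplained. This argues against them as the whole source for these genes, while a partial effect stays open. That interval was added after the R squared was seen.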

How the results depend on the processing

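The tests chosen only after the result was seen are those with a term for the replicates numbered 3, in replicates 1 and 2 alone, and without E16.5 mutant libraries 1 and 3. A 2-fold minimum, by its own construction, left 179 genes at E14.5, 1565 at E16.5, 1448 for the difference between ages, 4655 for age in controls and 2883 for age in mutants, with 73 genes shared between the ages in the same direction and 7 in opposite directions. DESeq2 called 2120 at E14.5, with 577 and 402 shared. The replicate block called 3155 at E14.5 and 6055 for the difference between ages, with 919 and 612 shared. A term for the replicates numbered 3 called 2938 at E14.5. Replicates 1 and 2 alone, with fewer samples, called 2286 at E16.5 and 1961 for the difference. The fit without E16.5 mutant libraries 1 and 3 called 2698 and 2017, and in it the differences for Stmn3 (-0.48) and Ina (-1.66) turned negative, neither of them called. Leaving out 1 library gave 526 to 1412 genes at E14.5 (666 without control library 1, 630 without control 3, 526 without mutant 1, 673 without mutant 2) and 2781 to 5486 at E16.5 (3079 without control library 1, 2781 without control 2).

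Shox2 at E14.5 passed the threshold, its log2 fold change little moved, with DESeq2 (0.2456, adjusted p = 0.0477), the replicate block (0.2511, adjusted p = 0.00335) and the term for the replicates numbered 3 (0.2486, adjusted p = 0.0137). The adjusted p ranged from 0.00335 to 0.278 over its alternatives. At E16.5 it lost its call in replicates 1 and 2 alone (0.6249, adjusted p = 0.0597) and without mutant libraries 1 and 3 (0.3447, adjusted p = 0.0682), with a range from 3.51e-06 to 0.0682. With an estimated correlation, camera called 0 lists at E14.5, 0 at E16.5 and 0 for the difference between ages (4, 5 and 5 at an unadjusted p under 0.05), and fry called 6, 16 and 15. Of the 12 lists called at E14.5, 11 kept their call in replicates 1 and 2 alone. Of the 13 lists called at E16.5, 11 kept their call with the replicate block and with the term for the replicates numbered 3. With no low-count filter, in 1 fit of all 12 samples, and in replicates 1 and 2 alone, 12 kept it in each. Without mutant libraries 1 and 3, 7 of the 13 lists called at E16.5 kept their call. Apart from settings that leave fewer samples, the cause of these shifts was not tested.

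Of 121 named genes at E16.5, the fit without mutant libraries 1 and 3 kept 94 calls or non-calls, weakened 26 and moved 1. DESeq2 kept all 121 there, and 102 at E14.5 with 3 strengthened. The 12 genes named for each age change kept their calls under each alternative that tested them (9 of 12 were tested with the 5 CPM filter in controls). The covariance of the E16.5 genotype effect with the control age effect, beyond unchanged groups, stayed negative, at -0.957 for genes called by age and -0.459 with the 5 CPM filter. Scaling by DESeq2 size factors shifts all genes alike and cannot move it. No scaling moved the median of all genes by over 0.1 on the log2 scale, and the median furthest from 0 was -0.0734 (upper-quartile factors, age in controls), against -0.00284 with TMM. In simulated data at this depth, 77.6% of 1.5-fold changes were recovered at E14.5, 61.5% at E16.5 and 42.2% for the difference between ages.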

Other observations

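Foxj1 and Rps2 were picked out only after their values were seen, and no tests beyond those of all genes were chosen after the results. With age, proliferation and vessel genes fell in controls: 31 of 32 cell cycle genes (list adjusted p = 5.38e-09, with an estimated correlation adjusted p = 0.0929) and 16 of 16 endothelial genes (adjusted p = 2.58e-07, with an estimated correlation adjusted p = 0.142) were lower at E16.5. The counts were the same adjusted over the list alone. In mutants all 32 cell cycle genes and 10 of 16 endothelial genes fell (32 and 12 adjusted over the list alone). Immediate early and heat shock genes rose in 15 of 18 cases and fell in 2 in both genotypes (16 and 2 adjusted over the list alone). Palate mesenchyme patterning factors fell in 22 of 27 cases in controls and 20 of 27 in mutants, the same adjusted over the list alone.

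Foxj1, the transcription factor of motile cilia, chosen after its values were seen, was at 400.2 to 477 CPM in E16.5 controls and at 104, 392 and 354 CPM in mutant libraries 1, 2 and 3. Rps2, a ribosomal protein gene also chosen so, was at 317, 15.4 and 147 CPM in those mutant libraries. Dlx1as, an antisense RNA, was at 61.8 ± 11.4 CPM in E14.5 controls and 2.495 ± 1.80 CPM in E16.5 controls, and reads of the opposite strand cannot be set apart, since the submitters give no strand setting.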
